A study of Mus musculus with 18 samples.

How the data were processed

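Expression was measured in 18 mouse embryonic stem cell samples, 1 array each, on 1-colour Agilent arrays. Per the labels, total RNA was taken with RNeasy kits and DNase, and 100 ng per sample was amplified and labelled with the Low Input Quick Amp kit. The labels name Cy5 as the dye, whereas the file headers describe 1 green scan channel; the disagreement does not enter the values. Per the file headers, the authors extracted the spots with Agilent Feature Extraction 12.0.1.1, which subtracts background, removes spatial trends and replaces the lowest values with a floor. The deposited processed signal is an intensity with no scaling between arrays. The authors' table of values holds the same intensity, since all 62976 spots were identical to the processed signal on each of the 18 arrays. The deposited median spot and local background intensities and the deposited spot flags (well above background, saturated, outlier; other values, not intensities) were also read. How the authors scaled the arrays for their own use is not given in the sources used here.

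The array carried 56605 probes, of which 32994 were matched to 22911 gene symbols by RefSeq transcript names, ignoring their versions. Probe positions were not used, so no coordinates are given. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 34197 probes, 23318 of them with a symbol. Of the latter, 107 were left out for outlier spots. Each gene was read from its probe with the highest mean signal, giving 16022 genes, 5698 of which had several kept probes. No spot was saturated. The processed signal was taken to log2 and each array's 75th percentile was subtracted, so every change is relative to that percentile. The arrays' number limits the precision, and signal over background limits which genes could be read.

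Groups followed the titles: arrays labelled Rescue or KO, titled 0h, 8h or 8h2h, with 3 arrays in each of the 6 groups. All 18 arrays entered 1 group-means model in limma 3.58.1 under R 4.3.3, with version 1.17.8 of the data.table package for reading. Each gene thus has 1 spread for all 6 groups, so the SE and adjusted p of a comparison also rest on arrays outside it. For 9 contrasts, genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided in the moderated test of limma, and all adjusted p values for genes come from it. The gene counts that moved one way and then back, or the same way in both lines, were set beside the product of the list sizes over all genes and beside 20 simulations with unchanged groups. Fixed gene lists, 16 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 144 tests, and again with an estimated correlation. Of the 47 calls at the preset correlation, 6 held with the estimated one: the ERK list in all 4 comparisons of 8h with 0h and 8h2h with 8h, and the trophoblast and cytoskeleton lists between the lines at 0h. Lists overlapped in part: 2 of the 28 tested ERK genes, 5 of the 24 naive genes and 6 of the 15 LIF and STAT3 genes stood in another list.

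The gene lists, the contrasts, the first alternatives below and the rule for named genes were fixed before the files were opened. By that rule, each contrast gave the 6 highest and 6 lowest changes among called genes that moved the same way on all 3 slides and whose symbols are not clone or predicted-gene names, up to 4 called members of each list with the largest change, and a fixed set of 20 genes whatever their values. The text names fewer than the rule gives, and a result withheld for evaluation is not reported here. Where no array of a group was well above background, the fold is written as "at least", computed against the gene's signal or, where higher, the lowest signal read well above background on each of those arrays, and no fitted fold is given. In an interaction with such a group the value is not a measured fold.

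Each alternative changed 1 choice: normexp background correction with an offset of 50, quantile normalization, the authors' table of values, no filter on dim probes, a filter over all 18 arrays, the mean of a gene's probes, the slide as a block, only the arrays compared, a trended and robust variance prior, a 2-fold minimum, and leaving out each array in turn. The files held no mean spot signal, so normexp used the median spot signal in its place. After seeing the data, 3 more were added: without a high-background array (replicate b of the KO-labelled arrays titled 8h2h), with unnamed probes, and with no scaling. The procedure was also tested on simulated data, drawn with each gene's mean and fitted spread and with known changes in 50 genes of each size between the Rescue-labelled 8h and 0h groups: 14% of changes of 0.5 on the log2 scale were recovered, 72% of changes of 1, 92% of changes of 2 and 64% of changes of -1, with 2 false calls among the unchanged genes and 0 calls in a contrast without changes. The simulated arrays were independent, with 1 spread per gene and no slide structure or array that stands apart, so these rates need not hold for the real arrays. A 2 h time after 4OHT, which the treatment text mentions, has no array among these and was not analysed here. Figures were drawn with matplotlib 3.10.9.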

Results

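RNA from mouse embryonic stem cells (strain 129SV) was measured on 18 arrays. Per the labels the cells lacked Esrrb, a nuclear receptor of the pluripotency network, and carried Raf-ErT2, a Raf kinase that 4-hydroxytamoxifen (4OHT) switches on, which activates Mek and then ERK. By the same labels, 9 arrays came from cells given an Esrrb transgene (labelled Rescue) and 9 from cells given an empty vector (labelled KO). In each line 3 arrays were titled 0h, 3 were titled 8h and 3 were titled 8h2h. Before treatment the cells spent 24 h in serum and LIF with 250 nM PD173074, an FGF receptor inhibitor, in place of the GSK3 inhibitor Chir99021. The treatment text gives 250 nM 4OHT for 8 h, and 4OHT for 8 h followed by a Mek inhibitor for 2 h. Replicates a, b and c were each 1 slide with all 6 groups, and each group held the same place on every slide, so place and group cannot be told apart. Deviations from the group means correlated at r over 0.1 in 28 of 45 pairs of arrays from 1 slide (median 0.141, highest 0.733). The main model leaves the slide out, and counts with the slide as a block are given beside. Nothing in the labels says that the letters were separate cultures, so each p measures the spread between these arrays only.

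The arrays differed in how much could be read. Between 53.6% and 63.8% of probes were well above background on the arrays labelled Rescue and between 46.6% and 56.4% on 8 arrays labelled KO. Replicate b of the KO-labelled arrays titled 8h2h stood apart, with 88.6% of probes well above background and a median negative-control signal of 42, against 24.5 to 28 on the others. Replicates correlated at r = 0.983 to 0.996 across genes, and this array correlated with its replicates at 0.943 to 0.945. It was kept, and the counts of called genes are also given without it. The list medians and list tests below include it. The 75th percentile of signal ran from 297 to 765 between arrays. Without scaling to it the median of all genes shifted by 0.07 to 0.47 on the log2 scale in the 7 comparisons of groups, most (0.47) in KO-labelled arrays titled 8h2h against 0h, and all changes below are relative to that percentile.

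The titles and the source names disagreed on 12 arrays: those titled 8h carried a source name with the Mek inhibitor, and those titled 8h2h carried one without it. Groups are named by title here, and neither treatment is assigned from the data. Of 5 fast ERK outputs fixed in advance, Dusp6 and the Sprouty genes Spry2 and Spry4 encode feedback inhibitors of ERK signalling, and Egr1 and Etv4 are transcription factors it induces. Each was lower on the array titled 8h2h than on the array titled 8h of the same slide, in 30 of 30 pairs. Dusp6 averaged 4.67 ± 0.09 (SD, n = 3, log2 scaled signal) on the Rescue-labelled arrays titled 8h and 0.43 ± 0.24 on those titled 8h2h, and the KO-labelled arrays gave 4.58 ± 0.05 and 0.17 ± 0.16. Etv4 differed by -0.12 ± 0.29 (SE, adjusted p = 1) and -0.33 ± 0.29 (adjusted p = 0.547), which did not pass the test.

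Esrrb itself gave signal in every group, and more of it on the arrays labelled KO. Rescue-labelled arrays averaged 4.40 ± 0.41 (SD, n = 3) at 0h, 1.91 ± 0.21 when titled 8h and 1.62 ± 0.13 when titled 8h2h. KO-labelled arrays averaged 5.03 ± 0.27, 3.75 ± 0.31 and 3.85 ± 0.54. It was higher on the KO-labelled array in 9 of 9 pairs from 1 slide and title, by 0.40 to 2.52. The difference at 0h was 0.63 ± 0.26 (SE, adjusted p = 0.118). Without the high-background array the difference was the same and its adjusted p was 0.0444. Whether the probe lies in the deleted part of the gene is not known, and every direction below between the lines rests on the KO and Rescue labels as given.

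**Figure D1:**
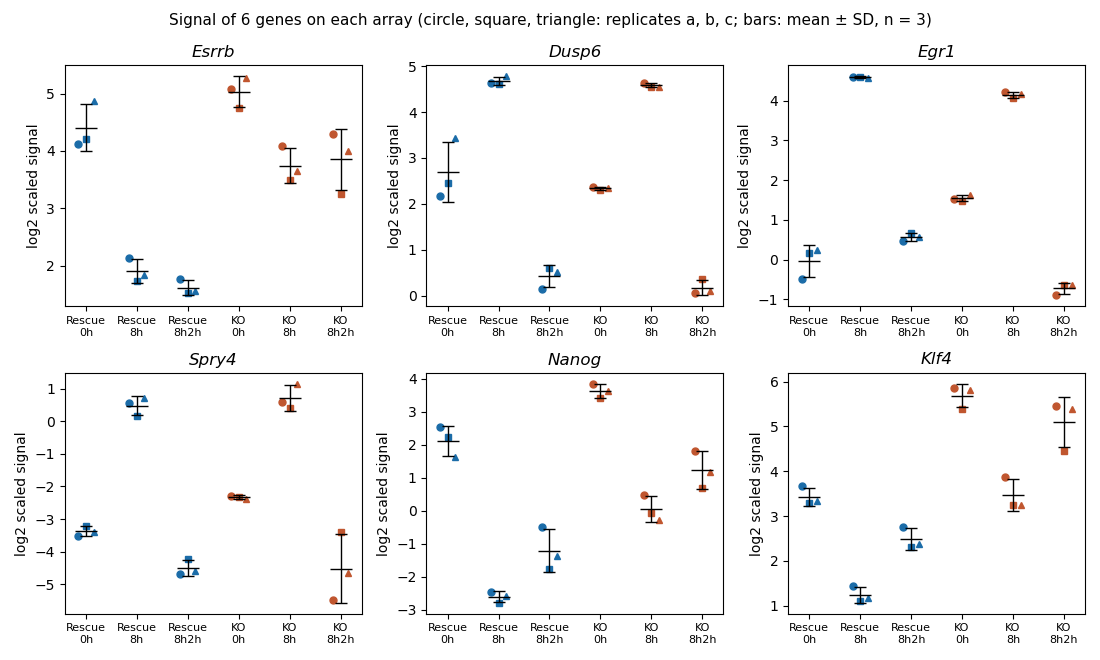
Log2 scaled signal of Esrrb, Dusp6, Egr1, Spry4, Nanog and Klf4 on each of the 18 arrays, by line and title. Points are arrays, shapes are replicates a, b and c, and bars are the mean and SD of 3 arrays. Esrrb on the KO-labelled arrays titled 8h lay between 3.50 and 4.09, above all 3 Rescue-labelled arrays of that title, and Dusp6 was lower on every array titled 8h2h than on every array titled 8h.

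The comparison of the lines at 0h asked how the cells differed before Raf was switched on. Trophoblast genes and actin cytoskeleton genes were lower on the arrays labelled KO. Of 15 trophoblast genes tested, 1 was higher and 11 were lower (1 and 12 adjusted over the list alone), with a median log2 change of -2.78, from -3.25 to -1.95 on single slides. Krt18, an epithelial keratin, fell by 3.68 ± 0.15 (SE, n = 3 per group), a 12.9-fold drop. Cdx2, a trophectoderm transcription factor, was at least 5.46-fold lower, Hand1 at least 5.46-fold and the placental gene Plac1 at least 15.8-fold, since no KO-labelled array at 0h read them above background. With such genes at their bound the median was -2.45. Among 19 cytoskeleton and SRF target genes, 14 were lower and 0 higher (15 lower adjusted over the list alone), with a median of -1.96, from -2.11 to -1.45 on single slides and -1.59 with bounds. The smooth-muscle actin-binding genes Tagln, at -4.51 ± 0.32, and Cnn1, at -3.21 ± 0.30, and the myosin light chain Myl9, at -2.74 ± 0.57, were among them. Fibroblast markers had 4 lower and 0 higher of 14 (the same adjusted over the list alone), with a median of -0.13, from -0.66 to -0.41 on single slides and 0.02 without scaling, and an adjusted p of 0.254. The trophoblast and cytoskeleton lists passed camera at the preset correlation (adjusted p = 3.02e-10 and 5.27e-12) and with an estimated one (adjusted p = 0.00517 and 0.0072).

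Naive pluripotency genes gave higher signal on the arrays labelled KO at 0h. Of 24 tested, 18 were higher and 1 lower, with the same numbers adjusted over the list alone, and a median of 1.07, from 0.82 to 1.54 on single slides. The transcription factors Tbx3 (2.42 ± 0.35), Klf4 (2.26 ± 0.25) and Tfcp2l1 (2.02 ± 0.35) were higher, each on 3 of 3 slides, and the junction gene Jam2 was 8.03-fold higher. Nanog differed by 1.51 ± 0.34 (adjusted p = 0.00669), a call that ended when the mean of its probes was used. The list gave an adjusted p of 2.7e-10, and an adjusted p of 0.187 with an estimated correlation. Of 15 LIF and STAT3 target genes, which share Klf4, Tfcp2l1, Klf5, Stat3 and Gbx2 with that list, 7 were higher and 1 lower (8 and 1 adjusted over the list alone), median 0.41, adjusted p = 0.000776, and adjusted p = 0.42 with an estimated correlation. The 12 core pluripotency genes split into 3 higher and 2 lower (the same adjusted over the list alone), with an adjusted p of 0.738.

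Most p53 targets were called lower on the arrays labelled KO at 0h. Of 29 primitive endoderm genes, 9 were lower and 1 higher (the same adjusted over the list alone), median -0.73, with an adjusted p of 0.023 that became 0.52 with an estimated correlation. Lrp2, an endocytic receptor, was lower (log2 -2.28 ± 0.21). Of 18 p53 target genes, 12 were lower and 1 higher (14 and 1 adjusted over the list alone), median -0.80, adjusted p = 4.09e-06, and adjusted p = 0.264 with an estimated correlation. The 18 ATF4 and amino-acid stress genes had 3 higher and 0 lower (the same adjusted over the list alone), adjusted p = 0.148. Among the p53 targets Perp changed by -2.42 ± 0.28 and the proapoptotic gene Pmaip1 by -1.09 ± 0.15. The 28 ERK genes moved both ways, 5 higher and 8 lower (6 and 9 adjusted over the list alone), with a median of -0.04 that was 0.11 without scaling, and an adjusted p of 0.641. Egr1 was higher by 1.58 ± 0.15, while Dusp4 (-1.72 ± 0.14) and Jun (-2.10 ± 0.28) were lower. Of 19 formative and primed epiblast genes, 4 were higher and 7 lower (5 and 7 adjusted over the list alone), median -0.41, adjusted p = 0.315. Pou3f1, a factor of the primed epiblast, was lower (log2 -1.88 ± 0.22).

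Across all 16022 genes, 2941 differed between the lines at 0h, 1136 higher and 1805 lower on the arrays labelled KO. With the slide as a block the count was 3522, and without the high-background array it was 4145. Of the called genes 99.6% had the same sign on all 3 slides, the arrays from which they were called. Outside the lists, Mymx, a myoblast fusion peptide, was 22.8-fold higher (log2 4.51 ± 0.37), Cobl, an actin nucleator, 16.2-fold higher, and Csf1, a macrophage growth factor, at least 13.2-fold lower. Without scaling 1011 genes were called, 465 higher and 546 lower.

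The change from 0h to the arrays titled 8h asked what followed 8 h of 4OHT, going by the titles. In the Rescue-labelled line, ERK feedback and immediate-early genes rose: 25 of 28 were higher and 1 lower (26 and 1 adjusted over the list alone), median 2.15, from 1.71 to 2.38 on single slides. Fosl1, an AP-1 subunit, rose 37.4-fold (log2 5.23 ± 0.47, SE), Egr1 24.7-fold, Spry4 14.4-fold and Dusp6 3.95-fold, and Egr3 rose at least 37.7-fold. The list's adjusted p was 8.36e-20, and 0.00366 with an estimated correlation. The chemokine gene Ccl20 rose 480-fold (log2 8.91 ± 0.34), and Aldh1a3, which makes retinoic acid, at least 119-fold.

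Several naive pluripotency factors fell in the same comparison. Nanog fell 26.5-fold (log2 -4.73 ± 0.34), Klf2 5.05-fold, Klf4 4.57-fold, Tfcp2l1 5.15-fold and Esrrb 5.63-fold (adjusted p = 6.48e-06). Of the 24 naive genes, which do not include Esrrb, 13 were lower and 4 higher (14 and 4 adjusted over the list alone), median -0.84, from -0.91 to -0.85 on single slides, adjusted p = 0.000776, and adjusted p = 0.566 with an estimated correlation. Manba, a lysosomal mannosidase in that list, rose by 2.50 ± 0.35. Core pluripotency genes moved both ways, 4 higher and 3 lower of 12 (4 and 4 adjusted over the list alone), adjusted p = 0.956, and Sox2 differed by 0.09 ± 0.14 (adjusted p = 0.69). The Nodal inhibitor Lefty1 fell 58-fold and Lefty2 4.4-fold. Among trophoblast genes 5 of 15 were higher and 1 lower (the same adjusted over the list alone), adjusted p = 0.09, with Hand1 up by 2.89 ± 0.51 and Cdx2 by 2.79 ± 0.34. Of 23 replication and cell cycle genes, 10 were lower and 1 higher (13 and 1 adjusted over the list alone), median -0.37, from -0.57 to -0.33 on single slides and -0.03 without scaling, adjusted p = 0.00316, and adjusted p = 0.615 with an estimated correlation. In total 4667 genes changed, 2086 higher and 2581 lower, with 5291 when blocked by slide and 5662 without the high-background array. Without scaling 2027 were called, 1635 higher and 392 lower, so the balance of directions depends on the scaling.

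ERK genes also rose in the KO-labelled line, 23 higher and 0 lower of 28 (26 and 1 adjusted over the list alone), median 2.11, from 1.81 to 2.10 on single slides. The list's adjusted p was 2.71e-20, and 0.00366 with an estimated correlation. Dusp4 rose 24.2-fold (log2 4.59 ± 0.14, SE), Spry4 8.22-fold, Egr1 6.08-fold and Dusp6 4.75-fold, while Ccl20 rose at least 280-fold. Formative and primed epiblast genes included 12 higher and 2 lower of 19 (13 and 2 adjusted over the list alone), median 0.95, from 0.73 to 1.02 on single slides, adjusted p = 9.53e-06, and adjusted p = 0.264 with an estimated correlation. In the Rescue-labelled line the same list had 5 higher and 5 lower (6 and 5 adjusted over the list alone), median 0.38, adjusted p = 0.143. In the KO-labelled line Pou3f1 rose 15.7-fold and Grhl2, an epithelial transcription factor, 4.33-fold. Cdx2 rose at least 37.5-fold, Hand1 at least 10.3-fold and Krt18 5.11-fold, although the trophoblast list as a whole, 6 higher and 3 lower of 15 (6 and 4 adjusted over the list alone), gave an adjusted p of 0.0649. Cdx2 averaged 0.79 (log2 scaled signal) on the arrays titled 8h in each line, so its larger fold here comes from its lower signal at 0h. Nanog fell 12-fold, Tbx3 5.75-fold, Klf4 4.68-fold and Klf2 4.14-fold, and Esrrb fell 2.43-fold (adjusted p = 0.00223). Of the naive genes 10 were lower and 4 higher (12 and 4 adjusted over the list alone), median -0.57, adjusted p = 0.0142, and adjusted p = 0.631 with an estimated correlation. In total 4077 genes changed, 1913 higher and 2164 lower, with 4645 when blocked by slide and 5037 without the high-background array. Without scaling 1828 were called, 1447 higher and 381 lower.

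Both lines moved largely together at 8h. Of the called genes, 1316 were higher in both and 1491 lower in both, where independent lists would share 249 and 349, and 32 moved in opposite directions, where 590 would. The shared genes numbered 2807 in all, 3218 when blocked by slide, 3464 without the high-background array and 1236 without scaling. Across genes, which are not independent replicates, the changes in the lines correlated at r = 0.758. Simulations with unchanged groups gave 0.00249, which was fixed in advance by independent draws for contrasts that share no arrays. The draws held no slide structure, so they do not test this correlation. The test of the difference between the lines called 365 genes, 171 with a higher and 194 with a lower change on the arrays labelled KO, 474 when blocked by slide and 755 without the high-background array. Without scaling the test called 54 genes, 14 and 40. It called 237, 184 and 218 without replicates a, b and c of the Rescue-labelled arrays titled 8h, 227 without replicate a of the KO-labelled arrays at 0h and 238 without replicate a of those titled 8h. Pou3f1 rose more on the arrays labelled KO, by 1.92 ± 0.31, as did the DNA methyltransferase Dnmt3a, by 1.91 ± 0.30, the corepressor Skor1, by 2.86 ± 0.29, and Krt18, by 1.70 ± 0.22. Pou3f1 and Krt18 started there from lower levels at 0h, so a larger rise need not mean a higher level at 8h. Egr1 rose less there, with a difference of -2.02 ± 0.22 (adjusted p = 0.000334), from a higher level at 0h. Cited1, a transcriptional coregulator, changed by -2.20 ± 0.30 and the sterol enzyme Msmo1 by -0.96 ± 0.18. The difference for Esrrb was 1.21 ± 0.37 (adjusted p = 0.135), and without the high-background array it was the same, with an adjusted p of 0.0368. Nanog (1.14 ± 0.48, adjusted p = 0.332) and Klf4 (-0.03 ± 0.36, adjusted p = 0.993) did not pass the test.

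**Figure D2:**
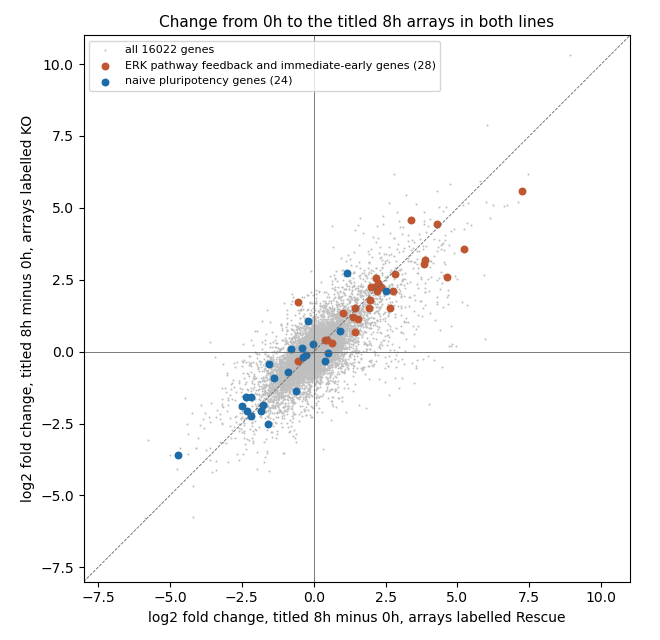
Log2 fold change of 16022 genes from 0h to the arrays titled 8h, on the arrays labelled Rescue (horizontal) and KO (vertical), 3 arrays per group. Grey points are all genes, orange the 28 ERK genes and blue the 24 naive pluripotency genes, and the dashed line marks equal change. The ERK genes had medians of 2.15 and 2.11, and Nanog lay lowest of the naive genes at -4.73 and -3.59.

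The arrays titled 8h2h against those titled 8h asked what followed 2 h with a Mek inhibitor, with the direction of the contrast given by the titles alone. By the treatment text the inhibitor came after the 8 h of 4OHT, so it goes together with 2 h more of culture. No array had that added time without the inhibitor, so inhibitor and time cannot be told apart. ERK genes fell in both lines. In the Rescue-labelled line 18 of 28 were lower and 0 higher (24 lower adjusted over the list alone), median -1.60, from -1.71 to -1.59 on single slides, adjusted p = 2.41e-52, and 0.000108 with an estimated correlation. In the KO-labelled line 20 were lower and 0 higher (21 adjusted over the list alone), median -1.49, from -1.87 to -1.42, adjusted p = 2.77e-32, and 0.00068 with an estimated correlation. Egr1 fell 16.3-fold and 29.3-fold in the lines labelled Rescue and KO (log2 -4.02 ± 0.15 and -4.88 ± 0.15, SE), Dusp6 19-fold and 21.3-fold, and the growth regulator Myc 12.6-fold and 19.2-fold. Spry4 fell 31.6-fold on the arrays labelled Rescue. On those labelled KO it was above background on only 1 of the 3 arrays titled 8h2h. Its signal there was highest on the high-background array (-3.41, against -5.50 and -4.65 on replicates a and c). Ccl20 fell 24.9-fold and 56.8-fold, and Nppb, a natriuretic peptide, 21.1-fold and 19.6-fold.

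Klf2 rose 3.66-fold and 3.92-fold on the arrays titled 8h2h. Foxd3, Otx2 and Gbx2, of the epiblast and pluripotency lists, fell. Foxd3 changed by -1.88 ± 0.21 on the arrays labelled Rescue and -2.43 ± 0.21 on those labelled KO, Otx2 by -1.62 ± 0.29 and -1.57 ± 0.29, and Gbx2, which stands in the naive and the LIF lists, by -2.69 ± 0.25 and -3.33 ± 0.25. The core list had 0 higher and 2 lower of 12 on the arrays labelled Rescue (4 lower adjusted over the list alone), median -0.26, adjusted p = 5.32e-05, and adjusted p = 0.164 with an estimated correlation. The KO-labelled line had 4 lower (5 adjusted over the list alone), median -0.35, adjusted p = 0.000418, and 0.243 with an estimated correlation. In the formative list 5 of 19 were lower in each line (5 and 6 adjusted over the list alone), medians -0.28 and -0.31, adjusted p = 1.19e-05 and 0.000221, and 0.264 and 0.336 with an estimated correlation. The naive list as a whole, 4 higher and 2 lower in each line (5 and 5, then 6 and 5, adjusted over the list alone), gave adjusted p values of 0.476 and 0.786. Klf4 differed by 1.25 ± 0.25 and 1.64 ± 0.25 and Nanog by 1.40 ± 0.34 and 1.18 ± 0.34. The Klf4 calls ended on the arrays labelled Rescue when any 1 of 3 arrays was left out and, on the arrays labelled KO, when only the compared arrays were fitted. The Nanog call on the arrays labelled Rescue ended without any 1 of 5 arrays and under 3 other settings, and on those labelled KO it was not called (adjusted p = 0.0508). Esrrb differed by -0.29 ± 0.26 and 0.10 ± 0.26, with adjusted p values of 0.969 and 0.844.

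In total 462 genes changed on the arrays labelled Rescue, 229 higher and 233 lower, and 578 when blocked by slide. Without the high-background array, which enters here only through the shared spread, 718 were called. Leaving out any 1 of the 6 arrays brought the count of 462 to between 228 and 276. Normexp background gave 336, 130 higher and 206 lower. KO-labelled arrays gave 1177 changed genes, 664 higher and 513 lower, 1493 when blocked by slide. The excess of higher genes was absent with normexp background (769, 382 higher and 387 lower) and with quantile normalization (816, 395 higher and 421 lower). Without the high-background array 934 were called, among them 760 of the 1177. Without replicate a of the KO-labelled arrays titled 8h the count was 769, and without replicate c it was 576. Fitted to the compared arrays alone, the counts were 1491 and 135, and without scaling they were 91, 38 higher and 53 lower, and 340, 253 higher and 87 lower. Between the lines, 9 genes differed in this change by limma, 8 with a higher and 1 with a lower change on the arrays labelled KO, with 12 when blocked by slide and 9 without the high-background array. At an unadjusted p under 0.05 there were 443, fewer than the 801 that would fall there with no change. The test thus gave fewer small p values than unchanged genes would, so its low counts do not show that the lines changed alike. Ackr3, a scavenging chemokine receptor, was 1 of the 9, at 1.63 ± 0.19 (adjusted p = 0.00335). The test called 16 without replicate a and 17 without replicate c of the KO-labelled arrays titled 8h2h. Quantile normalization left 3 (2 and 1), normexp 4 (3 and 1) and no scaling 5 (5 and 0).

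Genes that changed at 8h and moved back on the arrays titled 8h2h numbered 377 on the arrays labelled Rescue and 709 on those labelled KO, 467 and 885 when blocked by slide and 546 and 659 without the high-background array. Fitted to the arrays of each line alone they numbered 688 and 264, so the order of the lines turned round, and without scaling 76 and 185. Leaving out any 1 of the 6 Rescue-labelled arrays titled 8h or 8h2h gave 190 to 231, and leaving out replicate c of the KO-labelled arrays titled 8h gave 373. Among the former 198 rose then fell and 179 fell then rose, where independent lists would share 30.3 and 36.9, and 10 kept going the same way. Among the latter 345 rose then fell and 364 fell then rose, where independent lists would share 61.3 and 89.7, and 35 kept going. Both contrasts use the arrays titled 8h, which alone makes them correlate across genes, at r = -0.500 and -0.503 in simulations with unchanged groups, beside -0.535 and -0.445 here. The covariance was -0.177 and -0.216 against -0.0573 and -0.0583 simulated. With 3 arrays titled 8h in each line these could not be parted into separate sets for the contrasts, so part of the excess may come from the shared arrays. The genes that moved back were 198 of the 2086 risen and 179 of the 2581 fallen on the arrays labelled Rescue, and 345 of 1913 and 364 of 2164 on those labelled KO. Whether these shares differ between the lines was not tested.

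Against 0h, several pluripotency genes were lower on the arrays titled 8h2h. Nanog was lower on the arrays labelled Rescue (log2 -3.33 ± 0.34, SE), as were Esrrb (-2.78 ± 0.26) and Jam2 (-2.82 ± 0.36), while Klf2 no longer differed at the threshold (-0.46 ± 0.20, adjusted p = 0.114). In the KO-labelled line Lefty2 (-3.16 ± 0.26) and Jam2 (-2.23 ± 0.36) were lower, as were Nanog (-2.40 ± 0.34) and Esrrb (-1.18 ± 0.26, adjusted p = 0.00525). The Nanog call ended when the mean of its probes was used and the Esrrb call when only the compared arrays were fitted. Klf2 differed there by -0.08 ± 0.20 (adjusted p = 0.804). Of the naive genes 15 were lower and 1 higher on the arrays labelled Rescue (17 and 2 adjusted over the list alone), median -0.95, and 10 and 2 on those labelled KO (12 and 2), median -0.61. Their adjusted p values were 6.84e-07 and 0.000221, and 0.29 and 0.499 with an estimated correlation. Dusp6 was lower than at 0h (log2 -2.27 ± 0.23 and -2.16 ± 0.23), while Etv4 was higher (1.84 ± 0.29 and 1.45 ± 0.29). The ERK list had 12 higher and 6 lower of 28 on the arrays labelled Rescue (14 and 7 adjusted over the list alone), median 0.33, adjusted p = 0.0462, and 0.615 with an estimated correlation. On those labelled KO it had 9 higher and 6 lower (the same adjusted over the list alone), with a median of 0.12 that quantile normalization turned to -0.09 and normexp to -0.02, and an adjusted p of 0.663. Aldh1a3 was at least 80.2-fold and at least 13.2-fold higher, and S100a4 16-fold and 12.6-fold higher. S100a4 belongs to the 14 fibroblast markers, of which 4 were higher and 0 lower in the Rescue-labelled line (5 and 0 adjusted over the list alone), median 0.64, adjusted p = 0.00794, and 0.264 with an estimated correlation. In the KO-labelled line 5 were higher and 0 lower (6 and 1 adjusted over the list alone), adjusted p = 0.0219, and 0.361 with an estimated correlation, and their median of 0.58 became -0.05 with quantile normalization. The trophoblast list had 5 higher and 1 lower of 15 on the arrays labelled Rescue (7 and 1 adjusted over the list alone), median 0.61, and 6 and 1 on those labelled KO (7 and 1), median 1.12, with adjusted p values of 0.0167 and 0.00509, and 0.336 and 0.264 with an estimated correlation. Cdx2 was 3.37-fold higher on the arrays labelled Rescue and at least 16-fold higher on those labelled KO. Its mean log2 scaled signal on the arrays titled 8h2h was -0.24 and -0.44, so the larger fold comes from the lower signal at 0h.

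In all, 3409 genes differed between the titles 8h2h and 0h on the arrays labelled Rescue, 1682 higher and 1727 lower, 4035 when blocked by slide and 4468 without the high-background array. On the arrays labelled KO 3595 differed, 1768 higher and 1827 lower, 4320 when blocked by slide and 3434 without that array, among them 2724 of the 3595. Fitted to the compared arrays alone, the KO-labelled count was 1200. Without scaling the counts were 1689, 1533 higher and 156 lower, and 2356, 2252 higher and 104 lower, so the split by direction is relative to the 75th percentile.

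**Figure D3:**
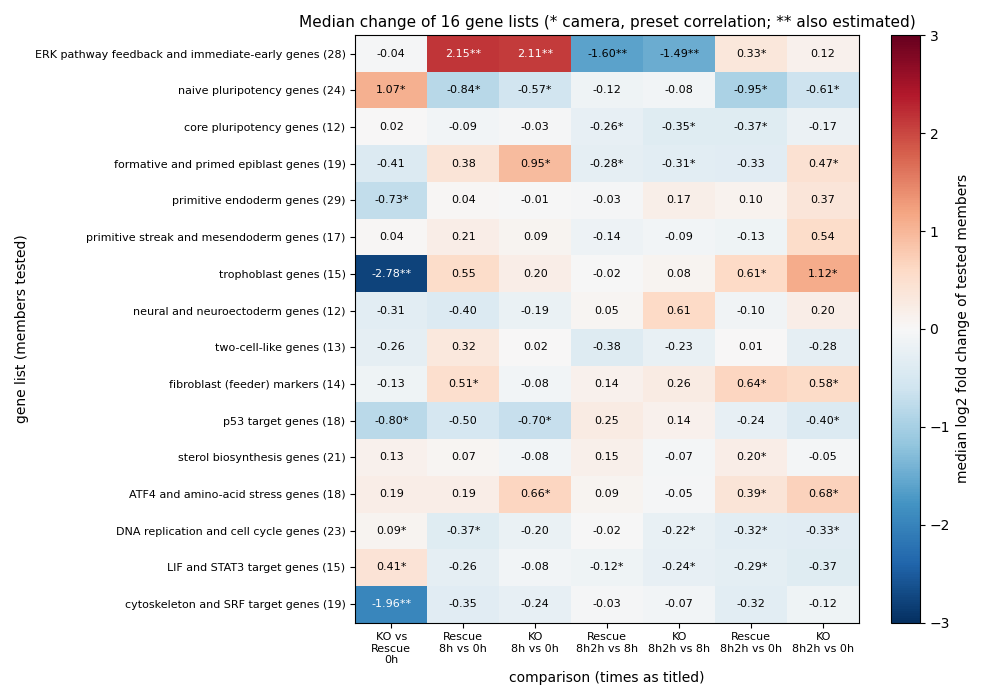
Median log2 fold change of the tested members of 16 gene lists (vertical, with the number tested) in 7 comparisons (horizontal, times as titled). Asterisks mark an adjusted p under 0.05 by camera at the preset correlation, and a pair of asterisks where an estimated correlation also passed. The ERK list moved from 2.15 and 2.11 at 8h to -1.60 and -1.49 in 8h2h against 8h, while the trophoblast and cytoskeleton lists were at -2.78 and -1.96 between the lines at 0h. Among the lists with an asterisk in a comparison, no scaling changed the sign of the medians of the core, cell cycle and LIF lists (Rescue, 8h2h against 0h) and of the p53 and cell cycle lists (KO, 8h2h against 0h), and quantile normalization turned the fibroblast list (KO, 8h2h against 0h) to -0.05.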

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

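The tests of the Esrrb signal and of the raised background were chosen after the results were seen, as was leaving out the array with high background. The test of a mislabelled sample was set after that array was seen to stand apart and before its own value was computed. The tests of the Mek labels, of the interactions and of other splits were planned, and the comparison of splits by the arrays they exchange was chosen after their counts were seen.

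The results in this paragraph stand out because the change from 0h to the arrays titled 8h differed between the lines by a test of the difference itself. It called 365 genes. A higher change on the arrays labelled KO was seen for Skor1 (2.86 on the log2 scale), Pou3f1 (1.92), Dnmt3a (1.91), Krt18 (1.70), Gbx2 (1.58), Lrp2 (1.40), Nr0b1 (1.26), Tfap2a (1.24), Dusp4 (1.22), Thy1 (1.18), Amn (1.18), Zfp42 (1.12), Tdh (0.87) and Lin28a (0.85). A lower change there was seen for Msmo1 (-0.96), Sox21 (-1.09), Cdkn1a (-1.18), Cdh2 (-1.40), Egr1 (-2.02), Cited1 (-2.20) and Ano1 (-4.57), the last of which was above background on only 2 of 3 arrays in 2 groups. Of these, Skor1, Pou3f1, Dnmt3a, Krt18, Msmo1, Egr1, Cited1 and Ano1 were called under every alternative run on them, and the others lost the call under at least 1. Pou3f1, Krt18, Lrp2 and Dusp4 were lower and Egr1 was higher at 0h on the arrays labelled KO. For these genes a different change need not mean a different level at 8h. Among the lists, the formative genes differed by a median of 0.66 (adjusted p = 0.000478), the sterol genes by -0.17 (0.0154), the ATF4 genes by 0.28 (0.023) and the cell cycle genes by 0.22 (0.0196), and with an estimated correlation the adjusted p values were 0.369, 0.624, 0.657 and 0.652. On the 12 arrays of the 4 groups alone the test called 433 genes, and 5 of 100 splits of these arrays gave as many, with a highest other count of 5527. By the share of 0.05 set beforehand, chance is not excluded. This share cannot decide the question, since the other splits that gave as many carry the difference between the lines into the test. Of the other splits, 40 exchanged equally many arrays between the lines at both titles and called 0 genes each. These mix arrays of both lines in each group, which widens the spread there, so few calls were to be expected. The other 59 exchanged unequal numbers, which carries part of the difference between the lines into the test, and 4 of them gave as many genes as the real one. The highest count came from the split that exchanged all arrays of the lines at 1 title and 0 at the other. By construction it tests the difference between the lines, a structure of the samples already given by the comparison at 0h, and it says nothing about the change at 8h.

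In the change from the arrays titled 8h to those titled 8h2h, the same kind of test called 9 genes. Measured in all 4 groups were Bhlhe40 (1.83), Ackr3 (1.63) and Txnip (-1.15), of which only Ackr3 was called under every alternative run on it. The sterol list differed by a median of -0.16 (adjusted p = 0.0139, and 0.615 with an estimated correlation) and the cell cycle list by -0.22 (2.89e-05, and 0.436). On the compared arrays alone the count was 9, and 6 of 100 splits gave as many, with a highest other count of 5941. Chance is not excluded here either, though the share cannot decide it, for the same reason. The 40 splits with equal exchange, which again mix the lines within groups, called 0 genes each. Of the 59 with unequal exchange, 5 gave as many. The highest count again came from exchanging all arrays of the lines at 1 title and 0 at the other, so it tests that same structure of the samples and not the change.

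Titles and source names disagree on which arrays had the Mek inhibitor, and a Mek inhibitor lowers ERK output. The ERK list had a median change of -1.60 on the arrays labelled Rescue and -1.49 on those labelled KO, titled 8h2h against titled 8h, and Dusp6, Spry4, Egr1, Etv4 and Spry2 were lower in 30 of 30 pairs from 1 slide. These values argue against the source names being right and the titles exchanged, which needs them to be positive, and are those that right titles with exchanged source names would give. Etv4 differed by only -0.12 and -0.33 and was not called. No biological explanation was tested, and the labels themselves remain to be settled by the depositors' records.

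Esrrb signal is higher on the arrays labelled KO, in 9 of 9 pairs from 1 slide and title, although that line lacks the transgene per the labels. The KO and Rescue labels may be exchanged, or the labels may be right and the probe may read transcript left by the knockout allele. The naive pluripotency list, which leaves Esrrb out, was higher on the arrays labelled KO at 0h by a median of 1.07. Single slides gave 0.82 to 1.54, and of 24 genes 18 were called higher and 1 lower. Camera at the preset correlation gave an adjusted p of 2.7e-10. This is the direction that exchanged labels would give. For these genes at 0h it argues against right labels with leftover transcript, which need the list to be lower there. It does not settle the matter, since the list's adjusted p with an estimated correlation was 0.187. The requirement on that p was added after the values were seen: the first wording asked only for at least 8 of 9 pairs and a positive naive median, which these values meet, and it was tightened because the pairs restate the pattern. A biological difference in Esrrb between the lines was not tested, and the probe's place relative to the deletion is not known.

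Replicate b of the KO-labelled arrays titled 8h2h stands apart from its group. A mislabelled sample is argued against by the brightest 25% of genes, where the array correlated with the other 2 replicates at 0.991 and with the next group, the KO-labelled arrays titled 8h, at 0.983, a gap of 0.00858. Raised background may account for it, since the dimmest 25% of genes lay 1.91 above the other replicates. The brightest 25% lay at -0.292, outside the 0.25 that had been set as the bound for this explanation, which made no allowance for the shift of the scaling percentile, so the test leaves it undecided. No biological explanation was tested for a single array.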

How the results depend on the processing

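Leaving out the high-background array, adding unnamed probes and dropping the scaling were chosen after seeing the data; the other alternatives were planned. Of 592 results for named genes 497 were called, and 306 of these calls held under every alternative run on them while 191 ended under at least 1. Of 47 list calls 41 ended with an estimated correlation. Without the high-background array 7 list calls ended and 2 were gained. Quantile normalization ended 9 and gained 4, and the filter over all 18 arrays ended 8 and gained 1. No filter on dim probes ended 2 and gained 16, so the number of lists called depends on that filter. The authors' table of values holds the same intensities, so it could change nothing and is no check of the results. The slide as a block kept all 12 counts within 1.5 times, and so did the mean of a gene's probes.

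Counts are given for KO against Rescue at 0h, then 8h against 0h, 8h2h against 8h and 8h2h against 0h in Rescue and KO order. A 2-fold minimum gave 1349, 1865, 1707, 211, 513, 1299 and 1384, with 174 and 280 genes moving back and 1125 shared at 8h, as fewer genes can pass. No scaling gave 1011, 2027, 1828, 91, 340, 1689 and 2356, with 54 and 5 for the interactions at 8h and 8h2h, 76 and 185 moving back and 1236 shared. Normexp gave 769 for 8h2h against 8h in KO and 4 for its interaction, which was 3 with quantile normalization, 3 with probes above background on all 18 arrays, 4 with a trended and robust prior and 14 with unnamed probes, where more features were tested. No filter gave 236 for the interaction at 8h, with more genes tested. Only the compared arrays gave 1491 and 135 for 8h2h against 8h in Rescue and KO, 1200 for 8h2h against 0h in KO, and 688 and 264 moving back. The spread was then estimated from fewer arrays, which in Rescue leaves out the high-background array and in KO at 8h2h keeps it. Without the high-background array, 8h2h against 8h in Rescue gave 718 and the interaction at 8h 755. Leaving out 1 array gave 228 to 276 for 8h2h against 8h in Rescue, 576 to 1298 in KO, 184 to 464 for the interaction at 8h, 7 to 17 for the interaction at 8h2h, and 190 to 431 and 373 to 704 moving back, where fewer samples were left and a group of 2 arrays is assumed to vary like the others. Zfp352 turned from -0.80, -1.37 and -1.16 to 0.159 (KO, 8h2h against 0h), 0.122 (Rescue, 8h against 0h) and 0.0459 (Rescue, 8h2h against 0h) with the mean of its probes, and the core list in the interaction at 8h2h turned to 0.0549 with quantile normalization. Apart from the constructions named, the cause was not tested.

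Signal over background limits the genes low on the arrays labelled KO, whose lowest processed signal was 2.50 to 6.01, and 6.85 on the high-background array, against 1.13 to 2.10 on those labelled Rescue. There a drop is often only a bound.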

Other observations

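No test in this part was chosen after its result was seen.

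Further values of gene groups fixed in advance follow. Of 18 ATF4 and amino-acid stress genes, 8 were higher and 0 lower on the arrays labelled KO at 8h against 0h (10 higher adjusted over the list alone), median 0.66, from 0.37 to 0.84 on single slides, adjusted p = 0.00113, and 0.571 with an estimated correlation. Chac1, which degrades glutathione, was 5.46-fold higher and Mthfd2, an enzyme of mitochondrial folate metabolism, 2.5-fold higher. In the Rescue-labelled line the list had 4 higher and 2 lower (the same adjusted over the list alone), adjusted p = 0.16. The 21 sterol biosynthesis genes split into 4 higher and 4 lower at 8h on the arrays labelled Rescue (the same adjusted over the list alone), adjusted p = 0.315, with Msmo1 at 1.59 ± 0.13 and Ebp at -0.94 ± 0.18. At 8h2h against 0h there, 7 were higher and 2 lower (8 and 2), median 0.20, adjusted p = 0.0219, and 0.631 with an estimated correlation. In the KO-labelled line 3 were higher and 2 lower in that comparison (the same adjusted over the list alone), median -0.05, adjusted p = 0.629. Of the p53 targets 10 were lower and 2 higher of 18 on the arrays labelled KO at 8h (the same adjusted over the list alone), median -0.70, adjusted p = 0.0119, and 0.615 with an estimated correlation. Phlda3 (-1.38 ± 0.20) and Btg2 (-1.49 ± 0.31) were lower, while Pmaip1 rose by 2.27 ± 0.15.

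Markers of other cell types were read as well. Of 14 fibroblast markers, which feeder cells would bring, 4 were higher and 0 lower at 8h on the arrays labelled Rescue (the same adjusted over the list alone), median 0.51, which was 0.08 with normexp background, adjusted p = 0.0171, and 0.336 with an estimated correlation, and S100a4 (3.81 ± 0.17), Thy1 (1.92 ± 0.19), Twist1 (1.83 ± 0.32) and Vim (0.99 ± 0.25) made up the 4. In the KO-labelled line 3 were higher (the same adjusted over the list alone), with a median of -0.08, a mean of 0.59 and an adjusted p of 0.122. Of 12 neural genes 1 was higher and 3 lower on the arrays labelled Rescue at 8h (the same adjusted over the list alone), adjusted p = 0.629, with Nes at 0.81 ± 0.13 and Tubb3 at -0.81 ± 0.21, and 1 was higher and 4 lower on those labelled KO (the same adjusted over the list alone), adjusted p = 0.264, with Sox21 at -1.58 ± 0.16. Of 17 primitive streak and mesendoderm genes 6 were higher and 3 lower at 8h on the arrays labelled Rescue and 7 and 3 on those labelled KO (the same adjusted over the list alone), adjusted p = 0.764 and 0.476. The mesoderm factor T was at least 2.63-fold higher on the arrays labelled KO, and Sp5, a Wnt target, 17.4-fold. Two-cell-like genes, 13 tested, had 0 higher and 1 lower in each line at 8h (the same adjusted over the list alone), adjusted p = 0.52 and 0.926, and Zscan4c differed by -0.09 ± 0.36 and -0.18 ± 0.36.

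Other ways of splitting the 6 arrays of each pair of groups were counted with only those arrays fitted. There are 10 such splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each of the 7 comparisons. The real counts were 1969 for the lines at 0h, 4704 and 3368 for 8h against 0h in Rescue and KO order, 1491 and 135 for 8h2h against 8h, and 3355 and 1200 for 8h2h against 0h, and the highest other count was 0 in each. Every other split puts arrays of both groups on each side, which widens the spread there, so few calls were to be expected.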
